A study of Homo sapiens with 8 samples.

How the data were processed

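The samples were CD34+ cells enriched from blood collected by leukapheresis from patients with multiple myeloma, 5 after a bortezomib-based treatment and 3 after filgrastim with cyclophosphamide. RNA was extracted with a micro-scale column kit, amplified as cDNA with a NuGEN Pico system, labelled with biotin and hybridized to Affymetrix expression arrays, per the labels' protocols. The values the authors deposited were used as given. They are taken to be log2 values, and the submitters' processing notes name GCRMA, a background correction and normalization for such arrays, without a version. The log base, the centring and the direction (higher meaning more RNA) are not given in the sources used here. Base 2 was taken because GCRMA returns it, and the widest probe set outside Y-linked genes, XIST and TSIX spans 9.27. The table holds 54675 probe sets on 8 arrays, and the median of every probe set over the arrays was 0 within 1e-06, so levels and signal over background are unknown. The medians of the columns over all probe sets were -0.036, -0.030, -0.021, 0.001 and -0.008 for bortezomib replicates 1 to 5 and 0.028, 0.072 and 0.086 for filgrastim and cyclophosphamide replicates 1 to 3. No pair of arrays held identical values: the highest correlation was 0.79. Each column was assigned by its sample's label and all columns were used.

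Probe sets were named through the annotation given for the platform, in which 41097 had 1 gene, 1801 several and 11777 none. Symbols were updated through Entrez IDs to the RefSeq gene table of GRCh38.p14, where 99.9% of the single-gene probe sets matched. Probe sets with several genes or none were left out of the gene table, as were the 62 control probe sets, Y-linked genes, XIST and TSIX. One gene named in advance had no single-gene probe set in the annotation and was not analysed here. The value of a gene was the mean of its probe sets, 41032 in all for 19740 genes, of which 9229 had 1. Among 10511 genes with several probe sets, 4391 had probe sets with fold changes of opposite sign, and among the 6015 of them that were called, 1470 did. A filter on values of at least 4 on 3 arrays, the same with 6, and a choice of the probe set with the highest mean had been set before the data were examined. They could not be applied to centred values, so no filter and the mean of the probe sets, both planned as alternatives, were used as the main setting.

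Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group as the only term, two-sided), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. There were 32 gene lists, 20 of cell programmes and 12 of cell types, set before the data were examined and tested with camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the 32 lists. A list's fry test asks whether its genes move one way on balance, and an exact permutation test compared the mean of its genes over the 56 splits of the arrays into 5 and 3. The smallest p of those splits is 0.0179. Array separation was the mean correlation of pairs within groups minus that between groups. The genes named in the text follow a rule set before the data were examined: the 15 largest increases and 15 largest decreases among genes past the threshold, up to 4 members per list by p, and 14 genes chosen for their role, 13 of them measured. Hybridization controls, the 3′ minus 5′ difference of GAPDH and the median of 120 olfactory and taste receptor genes, which blood cells are not known to need, were compared between groups by exact permutation. Figures were drawn with matplotlib 3.10.9.

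The fit was tested on simulated data with the residual spread of these 19740 genes, 200 of which were changed in the bortezomib against filgrastim and cyclophosphamide comparison, and with each gene centred on its median. It recovered 36% of 100 genes changed by 1 on the log2 scale and 89% of 100 changed by 2, with 3 false calls. The simulated genes were independent, and far fewer were changed than were called in the data, so these rates may not carry over. Set before the data were examined were the alternatives of quantile normalization, median centring of arrays, every probe set on its own, a variance trend with robust estimation, array weights, the GAPDH difference as a covariate, a replicate block, other thresholds, leaving out each array, other list tests and Spearman correlation. Added after the data were examined were a filter on spread, the probe set with the largest spread, centring on ribosomal protein and oxidative phosphorylation genes, the bioB controls as a covariate, list tests against the programme genes alone, and camera with an estimated correlation with each array left out.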

Results

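Blood stem and progenitor cells that had been mobilized into the circulation of patients with multiple myeloma were compared between 2 treatments. The cells were enriched from collected blood by CD34, a surface protein of such cells. The bortezomib group held 5 samples from patients given bortezomib, a proteasome inhibitor, with the glucocorticoid dexamethasone, with or without liposomal doxorubicin. The other group held 3 samples from patients given filgrastim, a recombinant form of the growth factor G-CSF, with the alkylating drug cyclophosphamide. The sample titles do not say whether patients of the bortezomib group also received filgrastim or cyclophosphamide before collection. RNA of each sample was amplified and hybridized to 1 expression array. The question put by this design is which transcripts differ between cells obtained after the 2 treatments. All values are on a log2 scale on which the median of each probe set over the 8 arrays is 0, so they give differences between arrays and no level of expression, and the number of arrays limits their precision. Fold changes are the mean of the 5 bortezomib arrays minus the mean of the 3 filgrastim and cyclophosphamide arrays.

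CD34 and most other genes chosen in advance for progenitor identity and adhesion were higher in the bortezomib samples. CD34 was 2.55 ± 0.23 higher on the log2 scale (limma, SE, 5 against 3 arrays, adjusted p = 5.95e-05), a 5.88-fold difference. KIT, the receptor for stem cell factor, was 2.31 ± 0.39 higher (adjusted p = 0.0012), and MPO, the myeloperoxidase of early myeloid cells, 2.14 ± 0.28 higher (adjusted p = 3.47e-04). CXCR4, the receptor that holds progenitors in the marrow through the chemokine CXCL12, was 1.76 ± 0.27 higher (adjusted p = 7.21e-04). ITGA4, the alpha chain of the integrin VLA-4, was 1.95 ± 0.33 higher (adjusted p = 0.00117). CD44, a receptor for hyaluronan, was 1.34 ± 0.26 higher (adjusted p = 0.00238), although its 13 probe sets ranged from -0.72 to 4.72. PSMB5, the proteasome subunit that bortezomib binds, was 1.88 ± 0.21 higher (adjusted p = 1.45e-04), and HSPA5, the main chaperone of the endoplasmic reticulum, 2.05 ± 0.32 higher (adjusted p = 7.88e-04). The remaining genes chosen in advance did not pass: CD38 differed by 0.33 (adjusted p = 0.0869), the stress factor DDIT3 by 0.36 (adjusted p = 0.37), the cycling marker MKI67 by -0.36 (adjusted p = 0.127), the erythroid factor GATA1 by -0.09 (adjusted p = 0.76) and the lymphoid enzyme DNTT by 0.89 (adjusted p = 0.185; 1.59 and adjusted p = 0.0185 without filgrastim and cyclophosphamide replicate 2). With each array centred on the genes of ribosomal proteins and oxidative phosphorylation, CD44 no longer passed (0.36, adjusted p = 0.232), GATA1 and MKI67 did (-1.06 and -1.33), and CD38, DDIT3 and DNTT turned to -0.65, -0.62 and -0.09. The bioB hybridization controls, bacterial transcripts added at hybridization and not RNA of the cells, also differed on these arrays, with a mean of -0.19 ± 0.20 (SD, n = 5) in bortezomib and 1.18 ± 0.31 (SD, n = 3) in the other group.

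**Figure D1:**
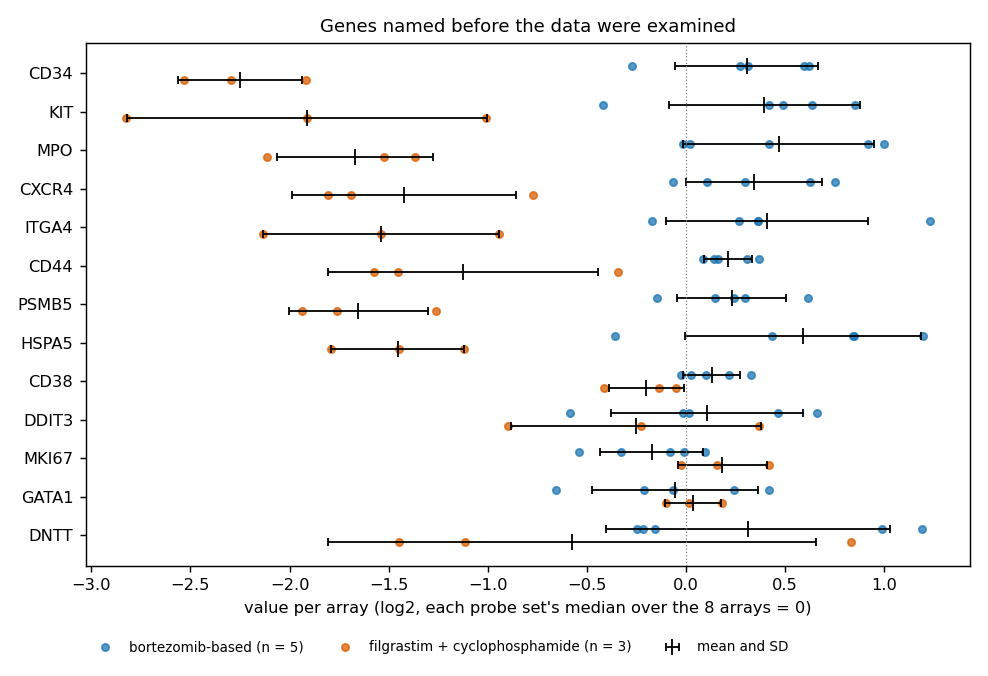
Each point is the value of a gene on 1 array on the log2 scale, with 5 bortezomib arrays in blue, 3 filgrastim and cyclophosphamide arrays in orange, and a black tick with a bar for the mean and SD of each group. The groups do not overlap for CD34, whose fold change was 2.55, while those of DDIT3, MKI67, GATA1 and DNTT lie across each other.

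Over all 19740 genes, 10352 (52.4%) differed at an adjusted p under 0.05 (limma), of which 5002 were higher and 5350 lower in bortezomib. The larger changes lay mostly on the higher side: of the 4729 called genes that differed by 2-fold or more, 3446 were higher and 1283 lower. The 5th and 95th percentiles of the fold changes were -1.08 and 2.05, and the median was -0.16. Groups did not overlap for 4480 genes that were higher and 5005 that were lower, together 48.1% of the genes, where chance gives 3.57%. The balance of directions depended on the scaling between arrays. After quantile normalization 5371 genes passed, with 61.1% of them higher in place of 48.3%. That step gives all arrays the same spread, although the SD of the centred values over all genes averaged 0.35 in bortezomib and 0.86 in the other group. It therefore alters group differences by construction. With each array centred on the genes of ribosomal proteins and oxidative phosphorylation, 14901 genes passed, 10.9% of them higher. The median of all genes shifted by -0.98 in this scaling, which was chosen after the data were examined. Every fold change moves by that same amount, so a list or gene that turns under the centring is no separate check. With the bioB controls as a covariate, also chosen after the data were examined, 0 genes passed and 1760 had an unadjusted p under 0.05 (limma); this covariate parts the groups without overlap, so it takes up much of any group difference.

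The 15 genes with the largest increases in bortezomib differed in function, and no shared theme among them was tested. The chemokine CXCL8 was 4.55 ± 0.19 higher (adjusted p = 9.19e-06), a 23.4-fold difference. The early activation antigen CD69 was 4.43 ± 0.66 higher (adjusted p = 6.15e-04), the prostaglandin synthase PTGS2 4.18 ± 0.76 higher (adjusted p = 0.0017), the TGF-beta-inducible factor KLF10 4.21 ± 0.33 higher (adjusted p = 3.92e-05) and the costimulatory ligand TNFSF4 4.10 ± 0.28 higher (adjusted p = 2.47e-05). SRP9, part of the signal recognition particle, had the largest value of all, 4.72 ± 0.57 (adjusted p = 2.15e-04). The others were the phosphatase subunits PPP1CC and PPP1R15B, the prefoldin subunit VBP1, the lysosomal thioesterase PPT1, the peroxiredoxin PRDX4, the pyrophosphatase PPA1, the ubiquitin ligase RNF139, SERINC1 and C16orf54, with fold changes from 3.93 for RNF139 to 4.46 for PPP1CC.

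Of the 15 genes with the largest decreases, 5 were protein-coding and 10 were noncoding RNA genes or pseudogenes, and the probe sets of duplicated loci may not tell near-identical copies apart. ANKRD36B, which is protein-coding, was lowest, at -3.29 ± 0.32 (adjusted p = 8.54e-05). The small Cajal body RNAs SCARNA2 and SCARNA17 were at -3.07 ± 0.62 and -2.85 ± 0.45, the small nucleolar RNA SNORA74A at -2.84 ± 0.58 and the ribosomal RNA precursor RNA45SN5 at -2.47 ± 0.62. NPIPA1, a protein-coding member of a duplicated family, was at -2.96 ± 0.29, and the pseudogenes ANKRD20A11P, PMS2P3 and PMS2P8 were at -2.67, -2.51 and -2.22. LINC01181, LINC00342 and LOC105379426 were at -2.91, -2.58 and -2.24, and LINC01181 did not pass without filgrastim and cyclophosphamide replicate 2 (adjusted p = 0.0516). The other protein-coding genes were LENG8 at -2.64, the mucin MUC6 at -2.57 and TPGS1 at -2.27. With the bioB covariate SCARNA2, RNA45SN5, LINC01181, PMS2P3 and PMS2P8 turned to 1.16, 1.11, 2.36, 0.49 and 0.48, none past the threshold.

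Genes of protein breakdown and folding were higher in bortezomib, as was each of the 20 programme lists by camera against all other genes. Against the other programme genes alone, a test chosen after the data were examined, only the proteasome list passed. Its camera adjusted p was 0.0256 (0.985 with an estimated correlation), against 0.473 for heat shock and 0.94 for unfolded protein response genes. Of 38 measured proteasome subunits, 32 rose, none fell and the median was 1.65, with PSMD14 at 3.39, the immunoproteasome subunit PSMB8 at 2.72, PSMD2 at 2.22 and PSMA4 at 2.01. The count was also 32 when adjusted over the list alone, and camera gave an adjusted p = 1.5e-11 (adjusted p = 0.155 with an estimated correlation). Of 20 heat shock genes, 14 rose and 2 fell (median 1.46, camera adjusted p = 3.22e-05; adjusted p = 0.155 with an estimated correlation). The cochaperones DNAJA1 and DNAJB6 were 3.51 and 2.70 higher, the collagen chaperone SERPINH1 2.47 and HSP90AB1 2.00. In the unfolded protein response list, 15 of 29 rose and none fell. Its median was 0.76 as deposited (camera adjusted p = 1.78e-04, and adjusted p = 0.267 with an estimated correlation). With arrays centred on ribosomal and oxidative phosphorylation genes that median was -0.22. The disulfide isomerase PDIA6 was 2.68 higher, the stress sensor ATF6 1.82 and PDIA3 1.43. On the same arrays the bioB hybridization controls moved the other way, by -1.37. With these controls as a covariate the proteasome list passed (camera adjusted p = 0.0123). The heat shock and unfolded protein response lists did not (camera adjusted p = 0.0996 and 0.39).

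Genes of energy supply and translation were mostly higher on the deposited values. Of 58 oxidative phosphorylation genes, 43 rose and 2 fell (median 1.08, camera adjusted p = 2.04e-10; adjusted p = 0.239 with an estimated correlation), with COX7B at 2.68, NDUFS3 at 2.07 and UQCRC2 at 1.57. Of 51 ribosomal protein genes, 42 rose and none fell (median 0.95, camera adjusted p = 2.71e-10; adjusted p = 0.369 with an estimated correlation), with RPS23 at 1.72 and RPS15A at 1.65. With the bioB covariate the median of the ribosomal protein list was -0.32 (camera adjusted p = 0.13). The oxidative phosphorylation list had a median of -0.079 with the bioB covariate (camera adjusted p = 0.733). Among 22 glycolysis genes, 17 rose and 1 fell (median 1.19, camera adjusted p = 1.05e-05; adjusted p = 0.155 with an estimated correlation), with PGAM1 at 3.08, PFKM at 2.56 and PGK1 at 2.26. Cholesterol synthesis was mixed, with 10 of 18 higher and 3 lower: INSIG1, which restrains sterol synthesis, was 2.32 higher and HMGCS1 2.07 higher, while MVD fell by 1.30. Its median was 0.68 as deposited (camera adjusted p = 0.0221, and adjusted p = 0.407 with an estimated correlation). With the ribosomal and oxidative phosphorylation centring that median was -0.29. With the bioB covariate the cholesterol synthesis median was -0.017.

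Stem cell and adhesion genes rose in most but not all members. Of 32 stem cell genes, 21 rose and 3 fell (median 1.05, camera adjusted p = 4.03e-04; adjusted p = 0.267 with an estimated correlation). The median of the stem cell list was 0.07 with the ribosomal and oxidative phosphorylation centring. With the bioB covariate it was 0.18, and the list did not pass (camera adjusted p = 0.463). The aldehyde dehydrogenase ALDH1A1 was 2.88 higher, BCL11A 2.32 and MEIS1 1.68. Of 38 adhesion, homing and mobilization genes, 21 rose and 2 fell. The median was 0.75 as deposited (camera adjusted p = 4.89e-05, and adjusted p = 0.179 with an estimated correlation). It was -0.22 with the ribosomal and oxidative phosphorylation centring, and the list passed with the bioB covariate (camera adjusted p = 0.00459). The small GTPase RAC1 was 3.04 higher, the sialomucin CD164 2.51 and PECAM1 1.21, the last with probe sets from -0.62 to 2.43. Of 25 drug handling genes, 13 rose and 1 fell, with ALDH2 at 3.32, ALDH3A2 at 2.25 and the exporter ABCC4 at 1.20. The median of that list was 0.47 as deposited (camera adjusted p = 0.00528, and adjusted p = 0.267 with an estimated correlation). It was -0.51 with the ribosomal and oxidative phosphorylation centring, and the list did not pass with the bioB covariate (camera adjusted p = 0.334).

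Stress-responsive and signalling lists contained some of the steepest increases. Of 22 immediate early genes, 15 rose and 2 fell (median 1.57, camera adjusted p = 4.37e-04; adjusted p = 0.297 with an estimated correlation), with FOS at 3.73, FOSB at 3.66, the mRNA decay factor ZFP36 at 3.46 and KLF6 at 2.24. The median of the immediate early list was 0.59 with the ribosomal and oxidative phosphorylation centring. With the bioB covariate it was 0.53, and the list did not pass (camera adjusted p = 0.165). In the glucocorticoid-induced list 11 of 19 rose and none fell (median 1.03, camera adjusted p = 5.29e-04; adjusted p = 0.239 with an estimated correlation). The median of that list was 0.05 with the ribosomal and oxidative phosphorylation centring and 1.30 with the bioB covariate (camera adjusted p = 0.00146). FKBP5, a chaperone of the glucocorticoid receptor, was 2.20 higher, TXNIP 1.81 and SLA 1.74. Of 24 NF-kB targets, 12 rose and 4 fell (camera adjusted p = 0.013; adjusted p = 0.155 with an estimated correlation), with SOD2 at 2.96, BCL2A1 at 2.89 and NFKBIA at 1.44. Of 17 STAT3 and G-CSF response genes, 7 rose and 2 fell (camera adjusted p = 0.0366; adjusted p = 0.239 with an estimated correlation), with CEBPB at 2.32, MCL1 at 1.95 over probe sets from -1.12 to 3.94, STAT5A at 1.82 and STAT3 at 1.62. That list did not pass without bortezomib replicate 4 (adjusted p = 0.0869). Of 18 NRF2 targets, 10 rose and 2 fell (camera adjusted p = 0.0189; adjusted p = 0.175 with an estimated correlation), where TALDO1 was 3.04 higher and OSGIN1 fell by 1.70. Of 21 p53 targets, 15 rose and 3 fell (camera adjusted p = 6.73e-04; adjusted p = 0.155 with an estimated correlation), with CCNG1 at 3.86 and TRIAP1 at 3.06. The medians of the NF-kB, STAT3, NRF2 and p53 lists were 0.69, 0.66, 0.79 and 0.96 as deposited, and -0.28, -0.32, -0.19 and -0.02 with the ribosomal and oxidative phosphorylation centring. With the bioB covariate FOSB, SOD2 and STAT5A turned to -0.35, -0.47 and -0.12, none past the threshold. The NRF2 and p53 lists did not pass with that covariate (camera adjusted p = 0.234 and 0.399). The NF-kB and STAT3 lists did (each camera adjusted p = 0.039).

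Interferon and antigen presentation genes were also higher on the deposited values. Of 32 interferon response genes, 16 rose and none fell (median 1.28, camera adjusted p = 1.02e-04; adjusted p = 0.465 with an estimated correlation), with SAMD9 at 3.29, OAS2 at 2.76 and IFITM1 at 1.87. The fry test of that list gave an adjusted p = 0.0556. One sample, bortezomib replicate 5, had a list median of 1.73, against 0.04 to 0.35 in the other 4 bortezomib arrays. Of 13 HLA class II presentation genes, 10 rose and 1 fell (median 1.54, camera adjusted p = 0.00154; adjusted p = 0.356 with an estimated correlation), with HLA-DMA at 3.47 and HLA-DMB at 2.19. With the bioB covariate the median of the HLA class II presentation list was -0.087 (camera adjusted p = 0.733). Cell cycle genes differed less evenly. Of 31 DNA replication genes, 16 rose and 1 fell (camera adjusted p = 7.61e-04; adjusted p = 0.301 with an estimated correlation), with PCNA at 3.80 and RRM1 at 1.81. Of 30 proliferation and mitosis genes, 9 rose and 2 fell (camera adjusted p = 0.0357; adjusted p = 0.665 with an estimated correlation, 0.109 by fry and 0.0994 by exact permutation), where TPX2 was 2.26 higher and AURKB fell by 0.82. That list did not pass without bortezomib replicate 1 or 2 (adjusted p = 0.0709 and 0.0533) or without filgrastim and cyclophosphamide replicate 1 (adjusted p = 0.141). The medians of these cell cycle lists were 0.73 and 0.27 as deposited, and -0.25 and -0.71 with the ribosomal and oxidative phosphorylation centring. Neither passed with the bioB covariate (camera adjusted p = 0.13 and 0.557).

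**Figure D2:**
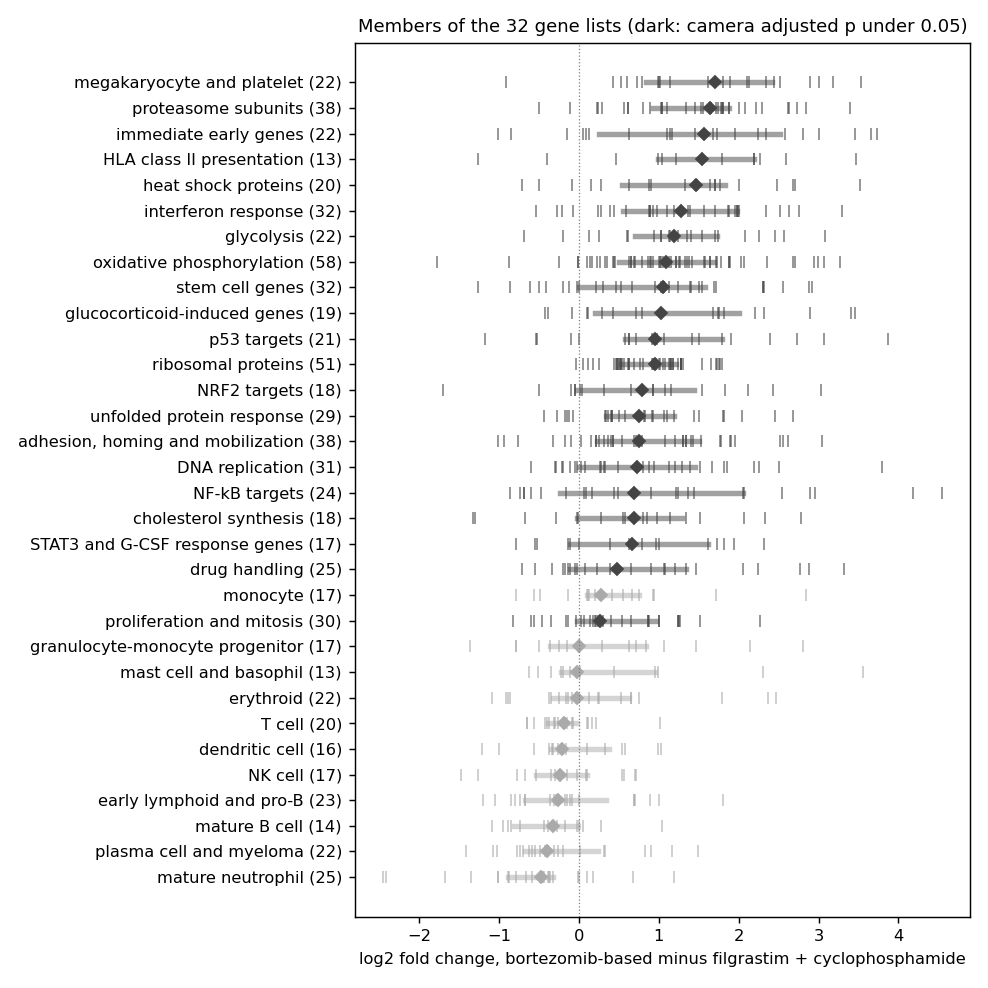
Each tick is the log2 fold change of 1 gene, bortezomib minus filgrastim and cyclophosphamide, in 1 of 32 lists with the number of measured genes in brackets; diamonds are medians, thick bars span the quartiles, and dark lists had a camera adjusted p under 0.05. Medians run from 1.71 for megakaryocyte and platelet genes to -0.47 for mature neutrophil genes.

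Of the 12 lists of cell type markers, 1 passed camera. Of 22 megakaryocyte and platelet genes, 10 were called higher in bortezomib and none lower (median 1.71, camera adjusted p = 1.26e-04; adjusted p = 0.378 with an estimated correlation). An exact permutation of the arrays gave that list an adjusted p = 0.0519. MMRN1 was 3.19 higher, the signalling regulator RGS18 3.53, the platelet selectin SELP 3.01 and PLEK 2.12. The array medians of the list overlapped between groups: -0.23, 0.81, 0.78, 1.81 and -0.05 in bortezomib replicates 1 to 5, and -0.14 at the highest in the other group. Bortezomib replicate 4, the highest of them, also had a monocyte median of 1.97, against -0.29 to 0.34 in the other 4 bortezomib arrays. The 11 other cell type lists did not pass camera, and 27.1% of all genes tested were called lower. Of 14 mature B cell genes, 6 fell and 1 rose (camera adjusted p = 0.119, fry adjusted p = 0.0032, exact permutation adjusted p = 0.0272). IGHM was at -1.08, over 5 probe sets from -1.97 to 0.46, and FCER2 at -0.88. Of 22 plasma cell and myeloma genes, 10 fell and 3 rose (camera adjusted p = 0.177; fry adjusted p = 0.0109; exact permutation adjusted p = 0.137), with SDC1, the plasma cell antigen CD138, at -1.08 and CCND2 at 1.49. Medians of the mature B cell and plasma cell lists were -0.33 and -0.40. The 120 olfactory and taste receptor genes had a median of -0.35, with 45 called lower and 1 higher. Fry and exact permutation do not compare a list with other genes. They therefore cannot tell a fall of these lists from that of the receptor genes. Of 17 NK cell genes, 5 fell and none rose (adjusted p = 0.306), with S1PR5 at -1.48 and NCR3 at -1.27. Of 25 mature neutrophil genes, 4 fell and none rose (adjusted p = 0.168), with PGLYRP1 at -1.35 and CXCR1 at -1.02. Without bortezomib replicate 5 its median was -0.82 (camera adjusted p = 0.0136; adjusted p = 0.601 with an estimated correlation). Of 20 T cell genes, 3 fell and 1 rose (adjusted p = 0.403), with BCL11B at -0.65 and SKAP1 at 1.01, the latter at 0.03 with the ribosomal and oxidative phosphorylation centring.

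Early lymphoid and pro-B genes went both ways, with 4 of 23 higher and 7 lower (adjusted p = 0.485), among them ADA at 1.80 and CD79B at -1.21. Of 16 dendritic cell genes, 2 rose and 3 fell (adjusted p = 0.606). TCF4 was at 1.03, over 8 probe sets from -0.27 to 1.61, and CLEC10A at -1.21. Of 17 monocyte genes, 2 rose, LYZ at 2.84 ± 1.02 and CLEC7A at 0.94 ± 0.28, the latter at -0.04 with the ribosomal and oxidative phosphorylation centring (list adjusted p = 0.306). The call of LYZ ended without bortezomib replicate 1, 4 or 5 (adjusted p = 0.0679, 0.0629 and 0.0575) and without filgrastim and cyclophosphamide replicate 1 or 2 (adjusted p = 0.137 and 0.163), and that of CLEC7A without filgrastim and cyclophosphamide replicate 2 (adjusted p = 0.0678). Of 17 granulocyte and monocyte progenitor genes, 5 rose and 4 fell (adjusted p = 0.522), with RNASE2 at 2.81 and CEBPE at -1.36. Of 22 erythroid genes, 4 rose and 3 fell (adjusted p = 0.553), with HEMGN at 2.46, KLF1 at 1.79 and HBQ1 at -0.87. Of 13 mast cell and basophil genes, 4 rose and 1 fell (camera adjusted p = 0.485; exact permutation adjusted p = 0.0272), with CPA3 at 3.55 and KIT at 2.31. With the bioB covariate HEMGN and CPA3 turned to -1.05 and -0.27, neither past the threshold. In the granulocyte and monocyte progenitor, erythroid and mast cell lists the median, at 0.00, -0.03 and -0.02, lay near 0 while the mean was 0.34, 0.21 and 0.48. Adjusted over the list alone, the counts of higher and lower genes were those given in 21 lists and changed in 11. Higher counts became 44 for ribosomal proteins, 44 for oxidative phosphorylation, 17 for DNA replication, 11 for cholesterol synthesis, 11 for HLA class II presentation, 12 for megakaryocyte and platelet genes and 0 for monocyte genes. Lower counts became 1 for glucocorticoid-induced genes, 1 for proliferation and mitosis, 1 for megakaryocyte and platelet genes, 2 for mature neutrophil genes and 1 for T cell genes.

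Whole-array profiles separated by treatment on average, with bortezomib replicate 4 an exception by correlation. The mean Pearson correlation of the centred values across genes, which are not independent, was 0.20 within bortezomib, 0.76 within filgrastim and cyclophosphamide and -0.42 between groups. Bortezomib replicate 4 correlated at -0.28 to -0.08 with the other bortezomib arrays and at 0.01 to 0.06 with the other group. The size and sign of these correlations depend on the centring of each probe set on its median over the 8 arrays. The within-group mean exceeded the between-group mean by 0.75 (two-sided exact permutation over 56 splits, p = 0.0179, the smallest these splits can give). The leading principal component, with 72.6% of the variance, separated the groups, with bortezomib arrays at 23.3 to 65.9 and the others at -95.0 to -68.4. The root mean square difference between arrays over all genes, which the centring leaves unchanged, was 0.24 to 0.43 among bortezomib replicates 1, 2, 3 and 5. Bortezomib replicate 4 was the bortezomib array nearest the other group, at 0.49 to 0.59 from its own group and 0.84 to 0.99 from the other. Without bortezomib replicate 1, 2, 3 or 5 in turn, the exact permutation p of the correlations was 0.0571. The hybridization controls separated them as well. Of the 4 controls added at hybridization, bioB and bioC were lower in bortezomib by -1.37 and -0.95 (each exact permutation p = 0.0179, adjusted p = 0.029 over 13 array measures), while bioD and cre differed by -0.02 and 0.00. The 12 probe sets for polyadenylated bacterial control transcripts were lower by -0.48 (exact permutation p = 0.0179, adjusted p = 0.029), and whether such transcripts were added to these samples is not stated. The median of 120 olfactory and taste receptor genes was -0.07 ± 0.04 in bortezomib (SD, n = 5) and 0.25 ± 0.01 in the other group (SD, n = 3). No filgrastim and cyclophosphamide array had a bioB value inside the range of the bortezomib arrays, so treatment and the difference between arrays cannot be told apart. P-values reflect the spread among these patients' arrays, and no batch was given in the labels.

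**Figure D3:**
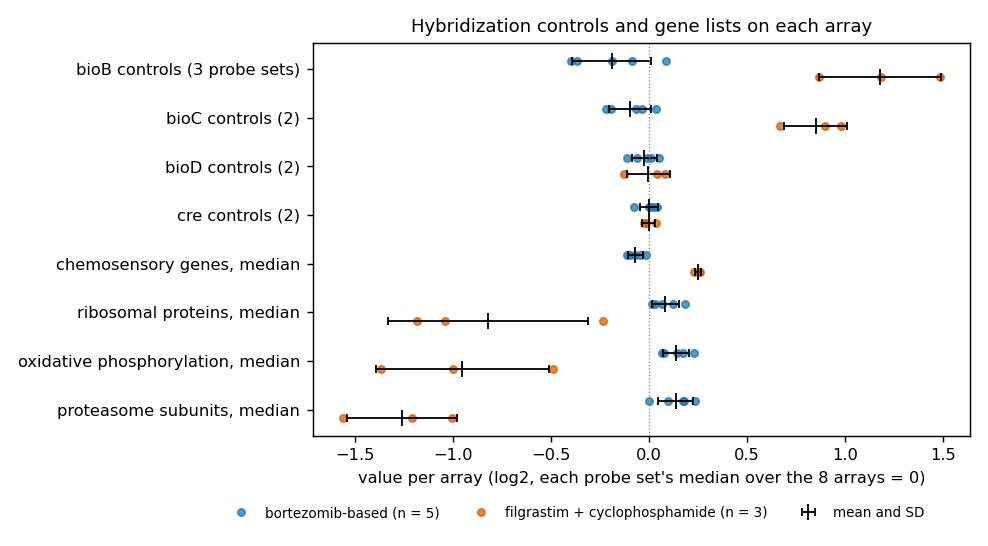
Points are the values of control probe sets, and the medians of gene lists, on each of the 8 arrays on the log2 scale, with 5 bortezomib arrays in blue, 3 filgrastim and cyclophosphamide arrays in orange and black ticks with bars for the mean and SD. The bioB controls differ by -1.37 and cre by 0.00, while the median of ribosomal protein genes lies lower on the 3 filgrastim and cyclophosphamide arrays.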

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

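All tests in this part except the count of splits and the GAPDH covariate were chosen after the results were seen. A sample far from the other 4 bortezomib arrays was looked for in 45 results, of which chance would give about 2.25, and 3 were found. The interferon response median was 1.73 in bortezomib replicate 5, against 0.04 to 0.35 in the others. In bortezomib replicate 4 the unfolded protein response median was -0.12, against 0.24 to 0.31, and the monocyte median 1.97, against -0.29 to 0.34.

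A total of 10352 of 19740 genes differed between the groups, with genes of basic cell machinery higher in bortezomib. Only the real split of the 56 splits of the arrays gave as many genes, and the highest other split gave 1. A random grouping of these arrays is argued against only to the smallest share these splits can give, 0.0179. Splits that mix the groups hold the group difference in their residual spread, so few calls were bound to occur there. With the GAPDH 3′ minus 5′ difference as a covariate 8578 genes still passed. That difference was 0.22, 2.58 and -0.21 in filgrastim and cyclophosphamide replicates 1 to 3, against -0.43 to 0.17 in bortezomib (exact permutation p = 0.125). It was high on 1 array and overlapped between the groups, so the covariate could take up little of a group difference. The same difference for ACTB went the other way, by 0.31. Loss of RNA toward the 5′ end as the whole cause is argued against only by this overlap. A signal difference between whole arrays is a candidate explanation: the bioB controls, which are no transcript of the cells, differed by -1.37, while bioD and cre, added at higher concentrations, did not. An effect of treatment on the cells stays open and cannot be told apart from it, since 0 of the 3 filgrastim and cyclophosphamide arrays had a bioB value inside the range of the bortezomib arrays.

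Immediate early and inflammatory genes were among the largest increases in bortezomib, with CXCL8 at 4.55, PTGS2 at 4.18 and FOS at 3.73. Against the other genes of the programme lists alone, the immediate early list gave a camera adjusted p = 0.94, and its median exceeded theirs by 0.61. The NF-kB list, which holds CXCL8 and PTGS2, differed in median from the other programme genes by -0.28 (adjusted p = 0.473). Whether these genes rose beyond the general rise of such genes therefore cannot be told apart with these lists: 5 of the 22 immediate early genes are in another list, and 2 fell while 15 rose. Induction by the treatment and by handling of the cells both stay open, as no test here separates them.

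Bortezomib replicate 4 stood apart from its group in genes of mature blood cells. Over all genes it lay nearer its own group, with a mean difference (root mean square) of 0.55, than the other, at 0.93. Its correlations of centred values, in contrast, were negative with the other bortezomib arrays and slightly positive with the other group. The monocyte median of this array exceeded the highest of the filgrastim and cyclophosphamide arrays, whose bioB values were higher, by 1.62. That gap alone cannot argue against an array-wide signal difference, since ribosomal and proteasome medians were also lower on those arrays. The bioB value of bortezomib replicate 4, 0.09, lay between the other bortezomib arrays (-0.40 to -0.09) and the filgrastim and cyclophosphamide arrays (0.87 to 1.49). Its monocyte median lay above both, which argues against a signal difference that follows bioB in 1 direction. Mature cells in the sample may be a source. It had the highest median of the 8 arrays in 3 of the 4 lists of monocyte, NK cell, T cell and platelet genes, the exception being NK cell genes at 0.30 against 0.42. These 4 lists were picked because the array stood apart in them, so the count is no independent support. The mature neutrophil list did not peak there, at 0.18 against 0.72 in bortezomib replicate 5 and 1.39 in filgrastim and cyclophosphamide replicate 3. The abundant transcripts LYZ, S100A9, GNLY and PF4 were 2.85, 3.46, 3.84 and 2.34 above the median of the other bortezomib arrays. CD34 enrichment would remove most such cells, 3 of the 17 monocyte genes are in another list, and a difference of progenitor state in this sample was not tested.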

How the results depend on the processing

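The filter, probe set, ribosomal and oxidative phosphorylation centring, bioB and programme-gene settings, and an estimated correlation with an array left out, were chosen after the data were examined. The filters on level and the choice of the probe set with the highest mean were not run, because the values hold no level; signal over background is unknown for the same reason. Counts of genes changed, higher and lower stayed within 1.5 times 10352, 5002 and 5350 under median centring, trend and robust estimation, array weights, the GAPDH covariate, an adjusted p under 0.10 and the probe set with the largest spread. Leaving out each array gave 8527 to 10939 changed, 4465 to 5242 higher, 4062 to 5697 lower, 20 to 22 lists at the preset correlation and a separation of 0.67 to 1.09 (exact permutation p from 0.0286 to 0.0571). Quantile normalization gave 5371, 3280 and 2091, all 5371 among the main calls. It makes the spread of all arrays alike, where the SD of the centred values averaged 0.35 in bortezomib and 0.86 in the other group. How far this lowered the counts was not tested, so they are no clear evidence about normalization. Every probe set on its own gave 22486, 10797 and 11689 because more features were tested. The share changed was lower, at 41.2% of 54554 probe sets against 52.4% of genes. A 2-fold minimum left 4729, of them 1283 lower, and the filter on spread left 3341 lower, by construction. The centring gave 1625 higher and 13276 lower, since it moves all genes by -0.98. With the bioB covariate, which parts the groups without overlap, 0 genes passed (0 higher and 0 lower; 1760 at an unadjusted p under 0.05, limma) and 9 lists, 1 of them new: monocyte, at 2.80 (adjusted p = 2.27e-05) from 0.27. The other lists that passed with this covariate were proteasome, NF-kB, glucocorticoid-induced, STAT3, interferon, adhesion, glycolysis and megakaryocyte genes. Of the 32 lists, 0 passed in camera with an estimated correlation (7 at an unadjusted p under 0.05), nor did any with each array left out as well. Of the 20 programme lists tested against programme genes alone, 1 passed, the proteasome (adjusted p = 0.0256), and it did not with an estimated correlation (adjusted p = 0.985); fry and exact permutation of arrays gave 21 each, of which 2 were other lists: fry lost interferon and proliferation and added mature B and plasma cell, and permutation lost proliferation and megakaryocyte and added mature B and mast cell. The NF-kB, NRF2, STAT3, proliferation and cholesterol lists did not pass with the filter on spread, nor did the STAT3 and cholesterol lists with the probe set of the largest spread.

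The replicate numbers do not pair the samples (correlations of deviations 0.10, -0.04 and -0.05); with them as a block 9213 genes and 23 lists passed, and 1 of the 3 filgrastim and cyclophosphamide arrays correlated best with its own number.

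Of the named genes that were called, CLEC7A -0.040 and PRG2 -0.029 changed direction with the centring. With the bioB covariate the direction given by camera turned for 2 lists that had passed, ribosomal -0.32 and cholesterol -0.017; the oxidative phosphorylation and HLA class II medians turned as well, to -0.079 and -0.087. Called genes that turned, on the log2 scale, were CAMP 1.27, CCND2 -0.064, CNRIP1 -1.01, CPA3 -0.27, FCER1A -1.15, FOSB -0.35, HEMGN -1.05, HLA-DPA1 -0.087, LINC01181 2.36, MGST1 -0.50, MSMO1 -1.38, PMS2P3 0.49, PMS2P8 0.48, PRDX1 -0.13, PTCRA 0.90, RNA45SN5 1.11, SCARNA2 1.16, SOD2 -0.47 and STAT5A -0.12, none past the threshold. Genes and lists that had not passed and changed sign are left out here. Of 161 named genes, 147 kept their direction and call after quantile normalization, 153 with the GAPDH covariate, 130 with the centring and 4 with the bioB covariate; the cause of these losses was not tested.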

Other observations

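The direction of change differed by kind of gene, a comparison chosen after the data were examined. Of 16504 protein-coding genes, 4865 (29.5%) were higher and 4274 (25.9%) lower in bortezomib. Of 2643 long noncoding RNA genes, 104 (3.93%) were higher and 846 lower, a different split of calls by Fisher's exact test (two-sided, p = 4.96e-153, genes not being independent). Of 418 transcribed pseudogenes, 22 were higher and 158 lower (Fisher's exact test, p = 3.25e-30). Of 120 olfactory and taste receptor genes, 1 was higher and 45 lower, with a median fold change of -0.35.

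Stem cell genes did not all move together. AVP, a marker of the earliest progenitors chosen here after its value was seen, was lower in bortezomib, at -1.26 ± 0.25 (SE, limma adjusted p = 0.0029), while ALDH1A1 and CD34 were 2.88 and 2.55 higher. Of all genes tested, 27.1% were called lower, and whether AVP lay above background cannot be told from centred values.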
